A study of Mus musculus with 23 samples.

How the data were processed

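Gene expression was measured in tumour cells and endothelial cells sorted from Py2T tumours. Py2T is a murine breast cancer cell line, grown here in the fat pad of female FVB/N animals. Some mice received nintedanib, a small molecule that inhibits VEGF, FGF and PDGF receptor kinases, at 50 mg per kg body weight. Sorted cells came from untreated tumours, from tumours treated for 7 days (short-term) and from tumours treated for 21 days (long-term). Per the series description, the untreated tumours were matched in size to the long-term tumours, so no untreated group of the short-term tumours' size was compared here. Each of the 23 samples was hybridised to 1 array, and the labels call the samples of a group biological replicates.

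The deposited values are log2 signals per transcript cluster. Per the submitters' processing notes, the authors used RMA and the oligo package, whose versions are not given in the sources used here. RMA corrects background, equalises the distribution of values between arrays and summarises probes on the log2 scale. Differences in the total RNA of the samples are removed by that step, so all changes are relative to the other transcripts of the same array. The labels list NuGEN kits for target synthesis. The values ran from 1.93 to 14.06, and the number of arrays per group, 3 to 5, limits the precision.

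The table held 35556 transcript clusters. In the platform annotation 21789 named 1 gene, 1621 named several genes and 12146 were not listed. Symbols were updated through the gene identifiers of the mouse RefSeq table (GRCm38.p6), which held 21698 of the single-gene clusters, and it was used for names alone. Where a gene had more than 1 cluster, as 999 genes did, the cluster with the highest mean over all 23 arrays was kept. This left 19938 genes, with no filter on dim clusters.

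Tests used limma 3.58.1 in R 4.3.3 (linear models with empirical Bayes moderation). Treatment groups were compared within each cell type, with the 12 tumour cell arrays in one fit and the 11 endothelial arrays in another. The difference of a treatment effect between the cell types, and untreated endothelial against untreated tumour cells, were tested in a fit over all 23 arrays. P-values were two-sided and adjusted by the Benjamini-Hochberg method within each comparison, and a gene was called at an adjusted p under 0.05. Errors beside log2 differences are standard errors of limma's fit. Shifts of 34 functional gene lists and 13 cell type marker lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 47 lists. Camera with an estimated correlation and fry were run beside it. Of the 836 symbols on the lists 773 were measured, 2 of them through an older name. The lists, tests and naming rule were fixed before the data were examined.

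The named genes are the 8 largest rises and 8 largest falls among the called genes of each treatment comparison. Left out were predicted genes, small RNAs with symbols starting with Mir, Snor or n-R, and olfactory or vomeronasal receptors. Scarna13 stayed in by this rule. Where fewer than 5 passed in a direction, the genes with the smallest p filled up to 5. Up to 4 members with the smallest p were taken from a described list, 6 genes per direction from a difference between cell types, and a fixed panel of transporters, glycolytic enzymes, hypoxia genes and angiogenic genes was added.

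The fits were tested on simulated data with 200 of 19938 genes changed. With each gene's sample SD as its spread, 2-fold changes were recovered in 87% of cases for short-term against untreated tumour cells and 85% for long-term against untreated. The same comparisons in endothelial cells recovered 56% and 56%, and 4-fold changes 82% and 84%. Of the simulated calls, 7.88% were false for short-term tumour cells, 7.54% for long-term tumour cells, 6.12% for short-term endothelial cells and 7.89% for long-term endothelial cells, all above the nominal 5%. With moderated SDs these shares were 9%, 2.51%, 2.16% and 3.75%. For long-term against short-term cells they were 2.54% in tumour cells and 5.3% in endothelial cells with sample SDs, and 7.08% and 6.29% with moderated SDs. Each share comes from 1 simulation per comparison and spread, so it is imprecise, and whether calls hold more false ones than the threshold states was not settled.

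Alternatives were a fit over all 23 arrays, filters at the 30th and 50th percentile of mean level, a trend in the prior variance, array weights, the mean of all clusters of a gene, renewed quantile normalization, median centring, leaving out each array, and the replicate number as a block. Leaving out 3 endothelial arrays high in macrophage markers, and macrophage or isolation stress marker means as covariates, were added after seeing the data.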

Results

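The data are 23 expression arrays of sorted cells from Py2T mammary tumours in FVB/N mice. Tumour cells were profiled on 3 arrays from untreated tumours, 4 from tumours treated with nintedanib for 7 days and 5 from tumours treated for 21 days. Endothelial cells were profiled on 3 arrays from untreated, 3 from short-term and 5 from long-term tumours. The series title names metabolic symbiosis and resistance to anti-angiogenic therapy as its subject. Pairs of arrays within a tumour cell group correlated at 0.983 or higher across genes, and pairs within an endothelial group at 0.935 or higher. The median residual SD of a gene was 0.156 log2 units in tumour cells and 0.255 in endothelial cells.

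Endothelial markers separated the sorted populations. Untreated endothelial arrays had higher levels of Pecam1 (by 7.07 ± 0.19 log2 units, SE), Cdh5 (7.92 ± 0.26), the VEGF receptor gene Kdr (6.31 ± 0.20) and Tek (6.21 ± 0.26), with n = 3 per group. All 22 measured endothelial markers rose, and all 22 also passed when adjusted over the list alone. The keratins Krt8 and Krt18 were lower in endothelial arrays by -2.45 ± 0.62 and -2.79 ± 0.61, with adjusted p = 0.00806 and 0.00253. Epcam (0.42 ± 0.34) and Cdh1 (-1.06 ± 0.38) did not pass, at adjusted p = 0.446 and 0.0613. Of the 19 macrophage and monocyte markers 1 was called higher and all 19 had positive differences, with a median of 1.17 and adjusted p = 0.00107 by camera, or adjusted p = 0.50 with an estimated correlation. In total 3656 genes differed, 1630 higher and 2026 lower in endothelial cells.

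In short-term tumour cells Galnt3, a glycosyltransferase, rose by 2.14 ± 0.19 log2 units (adjusted p = 0.00054), the matrix protein gene Postn by 2.02 ± 0.25 and Fermt1, a regulator of integrins, by 1.87 ± 0.22. The desmosome gene Dsp rose by 1.72 ± 0.31 and the chemokine gene Cxcl2 by 1.82 ± 0.35. Serinc2 (1.98), Crip1 (1.80) and Tmem47 (1.71) completed the largest rises. The largest falls were Rgl1 (-1.66 ± 0.14), Gas1 (-1.19), the macrophage elastase gene Mmp12 (-1.06), Nav3 (-1.04), the MAPK feedback gene Spry4 (-1.03), Fkbpl (-1.01), Terc (-0.94) and Tenm3 (-0.93). These groups held 4 and 3 arrays.

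Among the fixed lists, dissociation and immediate early genes shifted most in short-term tumour cells, with a median of 0.69. Of its 19 members 3 rose over all genes tested, and 15 passed adjusted over the list alone, 14 of them higher. Hspa1a rose by 1.63 ± 0.08, Dusp1 by 1.32 ± 0.20 and Zfp36 by 0.84 ± 0.16. The list had adjusted p = 1.05e-13 by camera, and adjusted p = 0.24 with an estimated correlation. Of 12 heat shock genes 3 rose, including Hspb1 (1.38 ± 0.15) and Dnajb1 (0.84 ± 0.15), and 5 passed adjusted over the list alone. Of 19 genes of the unfolded protein response 1 rose, Herpud1 (1.06 ± 0.19), all 19 had positive differences, and 4 passed adjusted over the list alone. Both lists had adjusted p = 0.24 with an estimated correlation. Of 31 mitosis genes 0 were called by limma and 0 adjusted over the list alone, while 29 had negative differences with a median of -0.35. That list had adjusted p = 1.04e-06 by camera and adjusted p = 0.58 with an estimated correlation. It turned direction with the isolation stress covariate, chosen after seeing the data, at adjusted p = 0.000716, in a range of 1.37e-15 to 0.576 over 24 alternatives. Macrophage markers also passed camera as lower in the same arrays, with a median of -0.18, 0 calls and adjusted p = 0.58 with an estimated correlation. Camera passed 14 of 47 lists, 0 with an estimated correlation and 3 by fry.

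In all, 101 genes changed in short-term tumour cells, 79 higher and 22 lower, and 56 of them by at least 2-fold. At an unadjusted p under 0.05 there were 2198, against 997 by chance. Of the 101 genes 101 kept their direction with the mean of the isolation stress genes as a covariate, chosen after seeing the data, but 1 remained called. The median change went from 1.04 to 0.93 and its median standard error from 0.16 to 0.26. Genes called in the same arrays for a large group difference favour a kept direction, so this does not decide on isolation stress. Array weights gave 67 genes and one fit over all 23 arrays gave 30. All 101 genes separated the groups without overlap, as did 10.2% of all genes against 5.71% by chance. For called genes this follows largely from the call itself, which needs a difference large against the spread, so it adds no support. The count was 24 without untreated replicate 3, 23, 28, 57 and 37 without short-term replicates 1, 2, 3 and 4, and 62 and 56 without long-term replicates 2 and 3, which enter through the shared spread.

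Glycolysis and hypoxia genes were higher in tumour cells of both treatment groups than in untreated ones. Glycolysis list means were 7.12, 7.34 and 7.52 in untreated, short-term and long-term tumour cells, and hypoxia list means 6.53, 6.79 and 6.91. In short-term against untreated cells both lists passed camera, but 0 of 47 lists passed with an estimated correlation. The values that follow are for long-term against untreated cells. Bnip3, a hypoxia-induced mitophagy gene, rose by 2.24 ± 0.25 log2 units (adjusted p = 0.00811), and the glycolytic genes Pfkp and Aldoa by 1.17 ± 0.17 and 0.63 ± 0.09, with n = 5 against 3. Of 19 measured glycolysis genes 2 rose over all genes, and 12 passed adjusted over the list alone, 11 higher and 1 lower. The median was 0.47, with adjusted p = 4.67e-09 by camera and adjusted p = 0.044 with an estimated correlation. Of 30 hypoxia genes 1 rose over all genes and 8 passed adjusted over the list alone. Their median was 0.30, with adjusted p = 7.81e-08 and adjusted p = 0.048 with an estimated correlation. Fry also passed both lists. In the same arrays 11 of 12 fibroblast markers had positive differences, with a median of 0.21, 0 called over all genes, 1 passing adjusted over the list alone, and adjusted p = 0.0231 by camera or adjusted p = 0.59 with an estimated correlation. Of 19 dissociation and immediate early genes 18 had positive differences, with a median of 0.31, 1 rising over all genes, 5 passing adjusted over the list alone, and adjusted p = 3.52e-07 by camera or adjusted p = 0.59 with an estimated correlation. Values that did not pass over all genes were Ldha at 0.50 ± 0.12, Hk2 at 0.47 ± 0.17 and the carbonic anhydrase gene Car9 at 0.67 ± 0.27. The lactate transporter genes Slc16a1 (0.20 ± 0.14) and Slc16a3 (-0.19 ± 0.07) did not pass either, at adjusted p = 0.674 and 0.407.

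**Figure D1:**
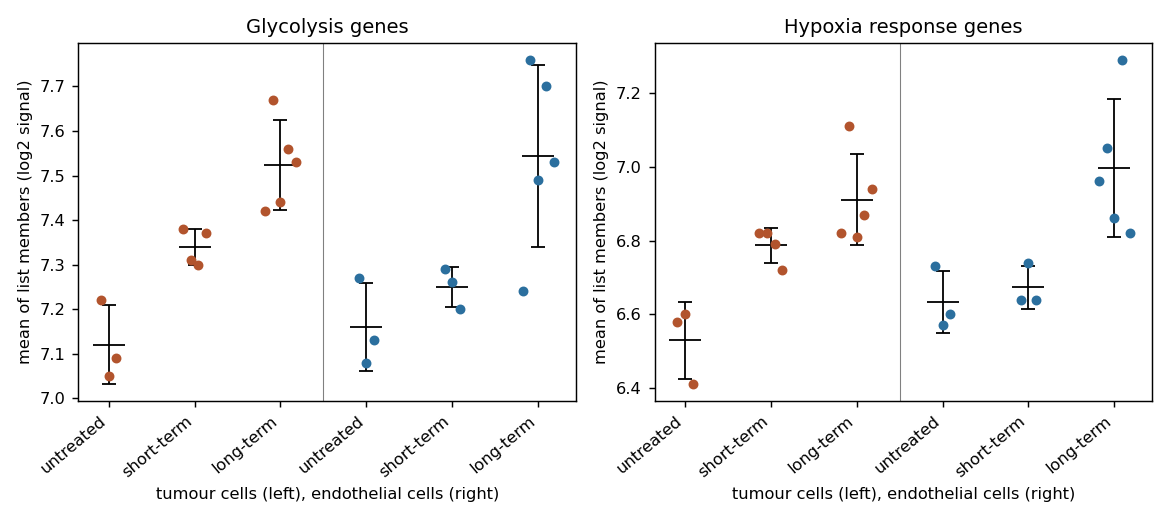
Mean log2 signal of the measured glycolysis genes (left) and hypoxia response genes (right) per array, by cell type and treatment; points are arrays, horizontal marks group means and bars SDs. The 5 long-term tumour cell arrays lie between 7.42 and 7.67 for glycolysis, above the 3 untreated arrays at 7.05 to 7.22. The 4 short-term tumour cell arrays, at 7.30 to 7.38, also lie above the untreated ones, and the axes do not start at 0.

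Other large rises in long-term tumour cells were Inmt (2.31 ± 0.31), the acute phase gene Saa3 (2.16 ± 0.28), the chemokine gene Cxcl14 (1.83 ± 0.21), Rarres1 (1.72 ± 0.27), Hspa1a (1.14 ± 0.08) and Prune2 (0.97 ± 0.13). Scarna13 (-1.53 ± 0.19) and Mmp12 (-1.24 ± 0.19) fell. Slc20a1 (-0.71), Terc (-0.89) and Tbxa2r (-0.61) did not pass. In total 18 genes changed, 15 higher and 3 lower. The count was 31 after median centring, 10 with array weights, 9 with one fit over all 23 arrays and 2 with the replicate number as a block. All 18 separated the groups without overlap, as did 6.03% of all genes against 3.57% by chance. The separation of the called genes follows largely from their selection and adds no support. The count was 30, 5 and 5 without untreated replicates 1, 2 and 3, 10 and 8 without short-term replicates 1 and 2, and 11 without long-term replicate 2.

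Of the genes called in both treatment groups, 4 were higher in both (Cxcl14, Hspa1a, Pfkp and Urod), 1 was lower in both (Mmp12) and 1 moved in opposite directions (Rgl1). Independent lists would share 0.0594 higher and 0.00331 lower genes. The comparisons share their 3 untreated arrays, which were too few to split. The covariance of their fold changes was 0.0243, against 0.0154 in 100 simulations with unchanged groups, while their correlation across genes was 0.481 against 0.597. The first is above and the second below the mean of the simulations. These drew each gene independently and give no range for genes that vary together, so neither difference decides whether the effects are shared.

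Of 31 mitosis genes all 31 had positive differences from short-term to long-term tumour cells, 4 rose over all genes, and 28 passed adjusted over the list alone. Nek2 rose by 1.00 ± 0.13, Birc5 by 0.80 ± 0.15, Ect2 by 0.99 ± 0.20 and Kif23 by 0.99 ± 0.21, with n = 5 against 4. The median of 0.77 had adjusted p = 5.65e-25 by camera and adjusted p = 0.34 with an estimated correlation. Of 26 DNA replication genes 0 were called by limma over all genes and 18 passed adjusted over the list alone, with a median of 0.43 and adjusted p = 0.34 with an estimated correlation. In the same comparison macrophage markers had a median of 0.18, with 15 of 19 positive, 0 called, adjusted p = 0.00561 by camera and adjusted p = 0.60 with an estimated correlation. Dissociation and immediate early genes had a median of -0.30, with 17 of 19 negative, 1 falling over all genes and 1 adjusted over the list alone, and heat shock genes -0.16, with 11 of 12 negative, 2 falling and 3 adjusted over the list alone. These lists had adjusted p = 0.54 and adjusted p = 0.34 with an estimated correlation. The mitosis list means of the 5 long-term arrays ran from 6.34 to 7.43, and those of the 4 short-term arrays from 6.05 to 6.40.

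The largest rises from short-term to long-term were Fgf7 (2.80 ± 0.50), a fibroblast growth factor, Foxf1 (2.70 ± 0.35), Saa1 (2.61), Angptl7 (2.60), Rgl1 (2.51 ± 0.12), Inmt (2.23), the Wnt inhibitor gene Dkk2 (2.15) and Masp1 (2.04). The vessel ligand gene Apln rose by 0.79 ± 0.13. The largest falls were Sprr1a (-2.28), Galnt3 (-2.28 ± 0.16), Fermt1 (-2.13), Il18r1 (-2.07), Nes (-1.95), Moxd1 (-1.83), Sectm1b (-1.82) and Tmem47 (-1.69). Of 17 TGF-beta targets 3 fell, among them Pmepa1 (-1.22 ± 0.20), Id1 (-0.90 ± 0.17) and Ltbp2 (-1.48 ± 0.31), and 4 passed adjusted over the list alone, with adjusted p = 0.51 with an estimated correlation. In total 243 genes changed, 124 higher and 119 lower. Of these, 52 had also been called between short-term and untreated cells, and 41 of them were raised in the short-term group. All 52 went in the opposite direction, which the shared short-term arrays favour: of genes at an unadjusted p under 0.05 in both comparisons 98.7% were opposite, against 98.6% in 100 simulations with unchanged groups. The number of genes was above that of the simulations: 861 at an unadjusted p under 0.05 in both, against a mean of 232 and at most 263, and 52 called in both in opposite directions, against a mean of 0.01 and at most 1, where few genes are called in either comparison. The correlation of the fold changes across genes was -0.601 against -0.488. The simulations drew each gene independently, so their highest counts give no range for genes that vary together. Of the 243 genes 240 separated the groups without overlap, as did 5.34% of all genes against 1.59% by chance. Again the separation of called genes follows largely from their selection. With the isolation stress covariate 57 were called, while all 243 kept their sign. The median change of the 243 went from 0.84 to 0.80 and its standard error from 0.14 to 0.17. A kept sign is favoured for genes called in the same arrays. One fit over all 23 arrays gave 96. The count was 122, 130, 119 and 95 without short-term replicates 1, 2, 3 and 4, and 128, 119 and 156 without long-term replicates 2, 3 and 4.

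In endothelial cells 0 genes were called by limma under short-term treatment, with 1629 at an unadjusted p under 0.05 against 997 by chance, and 2 without untreated replicate 1 or without short-term replicate 2. The gene with the smallest p was Arhgap11a (-1.30 ± 0.16, adjusted p = 0.193), followed in that direction by Zfp930, Kif11, Ergic2 and Dnase1l3. Tgm2 (0.83 ± 0.11), Epop (0.93 ± 0.15) and Serpina3n (2.58 ± 0.45) had positive differences that did not pass. Of 31 mitosis genes all 31 had negative differences, 0 were called over all genes and 20 passed adjusted over the list alone, with a median of -1.06. Examples are Top2a (-1.74 ± 0.29), Kif11 (-1.15 ± 0.18) and Cenpe (-1.23 ± 0.26), with n = 3 per group. The list had adjusted p = 7.03e-26 by camera and adjusted p = 0.29 with an estimated correlation. Macrophage markers also passed camera as lower in the same arrays. They had a median of -1.27, with 0 calls and adjusted p = 0.81 with an estimated correlation. Their means ran from 5.33 to 7.36 in untreated and from 4.52 to 4.90 in short-term endothelial arrays, without overlap.

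Tip cell genes had a median of -0.07 in short-term endothelial cells, with 0 called over all genes and 2 of 32 adjusted over the list alone, and adjusted p = 0.84 with an estimated correlation. Esm1 was at -2.26 ± 0.67 and Apln at -1.77 ± 0.51, both with adjusted p = 0.549. The receptor genes Kdr (-0.07 ± 0.25) and Flt1 (0.07 ± 0.28) differed by less than their errors. Of 19 dissociation and immediate early genes 7 passed adjusted over the list alone, with a median of 0.71 and adjusted p = 0.29 with an estimated correlation.

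**Figure D2:**
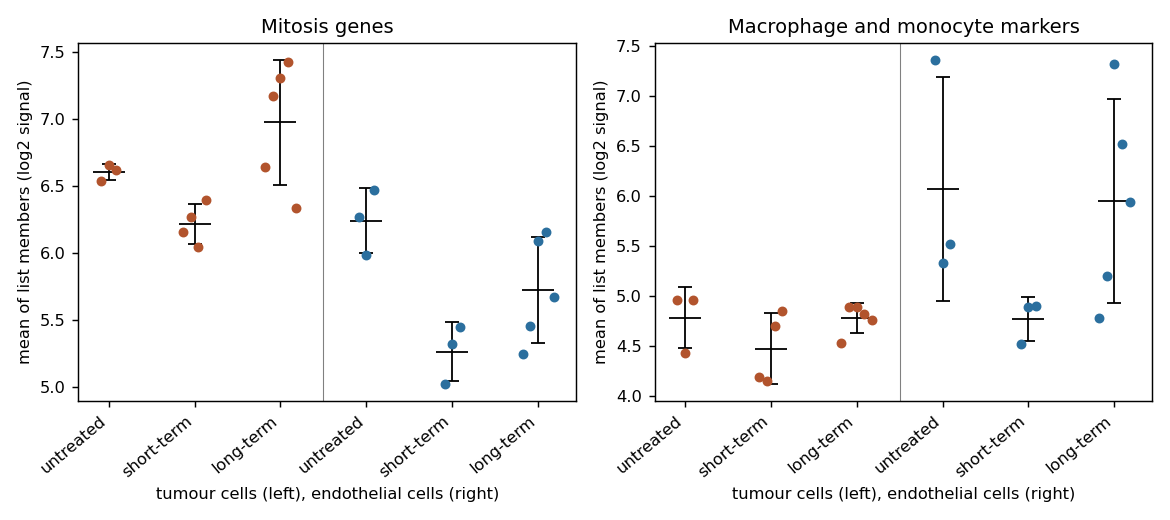
Mean log2 signal of the measured mitosis genes (left) and macrophage and monocyte markers (right) per array, by cell type and treatment; points are arrays, horizontal marks group means and bars SDs. The 3 short-term endothelial arrays lie at 5.02 to 5.45 for mitosis genes and at 4.52 to 4.90 for macrophage markers, and the axes do not start at 0.

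Under long-term treatment 0 endothelial genes were called by limma, with 833 at an unadjusted p under 0.05 against 997 by chance, and 1 without untreated replicate 1. Tgm2 (0.72 ± 0.10), Ccn4 (-1.03 ± 0.14) and Dnase1l3 (-0.63 ± 0.09) had the smallest adjusted p, 0.131, and Bnip3 was at 1.54 ± 0.25. Of 19 glycolysis genes 17 had positive differences, 0 were called over all genes and 2 passed adjusted over the list alone, with a median of 0.35. Of 30 hypoxia genes 22 had positive differences and 3 passed adjusted over the list alone, with a median of 0.27. Both lists had adjusted p = 0.14 with an estimated correlation. Mitosis genes passed camera as lower, with list means of 5.73 in long-term and 6.24 in untreated endothelial arrays. For this list 6 of 56 splits gave as small a p in either direction, and 0 lists passed with an estimated correlation. Of 19 dissociation and immediate early genes 10 passed adjusted over the list alone, among them Fos at 1.44 ± 0.24, with a median of 0.76 and adjusted p = 0.076 with an estimated correlation. Arterial markers had a median of -0.31, with Gja5 at -2.68 ± 0.62, 2 of 14 adjusted over the list alone and adjusted p = 0.18 with an estimated correlation. The mean of 100 tumour-specific genes ran from 6.90 to 8.81 in these 5 endothelial arrays and from 6.93 to 8.34 in the 3 untreated ones. Its average was 10.05 in long-term and 10.04 in untreated tumour cells. These genes were picked for the largest difference between the cell types. How much tumour cell RNA the endothelial arrays held was not tested.

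Long-term against short-term endothelial cells gave 0 called genes by limma, 1875 at an unadjusted p under 0.05, and 5 without short-term replicate 2. Camera passed 20 of 47 lists, 0 with an estimated correlation and 0 by fry. With one spread estimated over all 23 arrays, the endothelial comparisons called 106 genes for short-term, 34 for long-term and 262 for long-term against short-term. That spread includes the tumour cell arrays, whose residual SD is lower. Without the 3 endothelial arrays highest in macrophage markers, an alternative chosen after seeing the data, all of these comparisons again called 0.

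The short-term effect differed between the cell types for 19 genes, 6 with a higher and 13 with a lower effect in endothelial cells. This fit uses one spread for both cell types. The median residual SD was 0.255 in endothelial and 0.156 in tumour cells, so the error of the endothelial part may be understated. Galnt3 differed by -2.01 ± 0.23 (adjusted p = 0.000805), Kcnj2 by -3.04 ± 0.58, Sez6l2 by -2.11, Igfbp3 by -1.93, Sema3c by -1.89 and Nes by -1.73. Serpina3n (2.66 ± 0.48) and Rnf167 (2.16 ± 0.40) differed in the other direction. Without untreated tumour cell replicates 1, 2 and 3 the count was 7, 1 and 1, without short-term tumour cell replicates 1, 2 and 4 it was 6, 6 and 4, and without long-term tumour cell replicates 2 and 3 it was 5 and 9. Without short-term endothelial replicates 1, 2 and 3 it was 12, 138 and 11, without untreated endothelial replicate 3 it was 9, and without long-term endothelial replicate 4 it was 10. With array weights it was 11. The long-term effect differed for 0 genes by limma, with 1063 at an unadjusted p under 0.05 and 2 with array weights. Of 31 mitosis genes 30 had a lower long-term effect in endothelial than in tumour cells, with a median of -0.83, 8 passing adjusted over the list alone, and adjusted p = 0.28 with an estimated correlation.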

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

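The patterns, and all tests of explanations with markers or covariates, were chosen after the gene, list and marker results were seen. The bounds of these tests were set before their own values were computed, except for fibroblast RNA, the gene-by-gene covariate fit and tumour cell RNA as a covariate. The counts of other splits were planned.

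In tumour cells 52 genes differed in the short-term group from both other groups, 41 higher and 11 lower. The 52 genes were chosen because they show the pattern. Stress during cell isolation stays undecided. With the isolation stress mean as a covariate the signed score was 1.12 (SE 0.11) against 1.17 (SE 0.07) without it. But genes chosen in the same arrays for a group difference large against their spread favour a score that keeps its shift. The same covariate left 1 of 101 calls, because the median standard error rose from 0.16 to 0.26 while the median change went from 1.04 to 0.93, and group explains 63.2% of the covariate. For fibroblast RNA, the median shift of the 12 fibroblast markers was 0.07, upper limit 0.37, where 0.56 would be needed. This argues against a joint rise of the markers as the whole cause. The limit comes from resampling the markers and leaves out the variation between arrays. Against untreated cells 6 of the 12 were higher and 6 lower, with a median of 0.19, 2 called higher, 4 passing adjusted over the list alone and adjusted p = 0.58 with an estimated correlation, and 2 of the 12, Col1a1 and Postn, are among the 52 genes. An array batch shared by both cell types stays open. The same 52 genes shifted by 0.18 in endothelial arrays, with an upper limit of 0.29, also from resampling genes, against a bound of 0.27. An effect of treatment time or of tumour size also stays open.

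Mitosis genes were lower in endothelial arrays under short-term treatment, by -0.98 (SE 0.26) in the list mean, with 0 members called by limma over all genes and adjusted p = 0.29 with an estimated correlation. Isolation stress stays undecided. With the isolation stress mean as a covariate the change was -1.56 (SE 0.39). But that mean was 8.32 in untreated and 9.05 in short-term endothelial arrays, without overlap between the groups. The adjusted change therefore rests on the slope within small groups, which cannot separate isolation stress from treatment. Macrophage RNA stays open, since the change was -0.65 (SE 0.23) with the macrophage mean as a covariate and the bound was -0.49. For tumour cell RNA, the tumour-specific genes changed by -0.23 (SE 0.52), which decides nothing, but with their mean as a covariate the change was -0.90 (SE 0.20), which argues against it as the whole cause. An effect of treatment on endothelial division was not tested apart from these.

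Glycolysis and hypoxia genes were higher in endothelial arrays under long-term treatment, by 0.37 (SE 0.09) in the mean of both lists, with 0 members called by limma over all genes and adjusted p = 0.14 with an estimated correlation for each list. Macrophage RNA is argued against, since the difference was 0.38 (SE 0.10) with that covariate. For tumour cell RNA, the 100 tumour-specific genes differed by 0.35, above the bound of 0.19 set beforehand, but its SE is 0.47. The bound took no account of that error, and the requirement of 1 SE, by which the test is read as undecided, was added after the value was seen. With their mean as a covariate the difference was 0.34 (SE 0.09), which argues against tumour cell RNA as the whole cause. Isolation stress was not tested for this pattern and stays open. The isolation stress mean ran from 8.17 to 8.55 in untreated and from 8.80 to 9.50 in long-term endothelial arrays, without overlap. A response of the endothelial cells to treatment and other differences between the groups also stay open.

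Other splits of the same arrays were counted for each comparison, with the real split included. For genes in tumour cells, the real split alone called as many in each comparison. These were short-term against untreated (1 of 35 splits, 101 genes, highest other 1), long-term against untreated (1 of 56, 18 genes, highest other 6) and long-term against short-term (1 of 100, 243 genes, highest other 130). The same held for the different short-term effect (1 of 100, 19 genes, highest other 15). Such a share is under 0.05 per comparison and speaks against chance, with no adjustment over the comparisons. It cannot tell treatment from another difference between the groups, such as a batch. Where the real split called 0 genes every split is as large, so the count says nothing: long-term endothelial cells against untreated (56 of 56, highest other 1) and against short-term (56 of 56, highest other 3), and the different long-term effect (100 of 100, highest other 27). The 10 splits of short-term against untreated endothelial cells (0 genes, 10 splits as large, highest other 3) and of untreated endothelial against tumour cells (3656 genes, 1 split, highest other 0) are too few for a share under 0.05. The split with 130 genes sets long-term replicates 1 to 4 against the 4 short-term arrays with long-term replicate 5, and so differs from the real one by 1 array. The 27 genes of another split, where the real one gave 0, may come from a structure of the samples, from single arrays or from chance, which were not told apart by a test.

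For the number of shifted gene lists chance cannot be excluded in the following comparisons. In tumour cells the splits as large were 2 of 35 for short-term (14 lists, highest other 15), 9 of 56 for long-term (10, highest other 11) and 5 of 100 for long-term against short-term (13, highest other 14). In endothelial cells they were 14 of 56 for long-term (14, highest other 24) and 3 of 56 for long-term against short-term (20, highest other 20). For the differences between cell types they were 24 of 100 for short-term (8, highest other 12) and 76 of 100 for long-term (5, highest other 22). For short-term endothelial cells 5 of 10 splits were as large (6 lists, highest other 10), and 10 splits are too few. For single lists, glycolysis and hypoxia in long-term tumour cells each had 1 of 56 splits with as small a p in either direction, and mitosis in the same comparison had 19.

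Single arrays stood apart from their group in 39 of 882 tests, where chance alone gives about 44.1. These tests covered only the groups with 4 or 5 arrays. The untreated groups and the short-term endothelial cells, with 3 arrays each, were not tested. Among the endothelial arrays, short-term replicate 1 had the lowest array weight, 0.497, where the highest was 1.33. On the axis of largest variation between these arrays (first principal component, 20.2% of the variance) it was at 71.2. The others ran from -21 to 7.3. It is 1 of only 3 short-term endothelial arrays. In long-term endothelial replicate 4, Krt19 was at 9.56 (others 3.79 to 4.24), Krt7 at 7.91, Lcn2 at 8.09 and St14 at 5.01. In the other long-term endothelial arrays, Cenpe was at 4.45 and Acadm at 6.41 in replicate 1, Uqcrb at 8.18, Rgs5 at 4.96 and the fatty acid oxidation mean at 7 in replicate 2, Angpt2 at 6.96 and Mfap5 at 6.13 in replicate 3, and Pgam1 at 9.16, Slc20a1 at 9.28, Il18r1 at 3.26 and Lama4 at 10.75 in replicate 5. In short-term tumour cells, Inmt was at 3.82, Tpx2 at 5.86 and Syvn1 at 8.82 in replicate 1, Spry4 at 5.36, Hspa1a at 8.83, Sdhb at 9.93, Rpl10a at 12.37 and Rpl30 at 8.25 in replicate 2, Hk2 at 5.17, Id1 at 7.95, Zfp930 at 6.22, Ergic2 at 7.41 and the pentose phosphate and serine pathway mean at 7.24 in replicate 3, and Slc20a1 at 9.30 in replicate 4. In long-term tumour cells, Ndufa6 was at 9.55 and C1qb at 3.99 in replicate 1, Ccl3 at 4.83, Rnf24 at 6.81 and Creld2 at 7.80 in replicate 3, Spred2 at 8.70 and Fgfr1 at 8.91 in replicate 4, and Il18r1 at 6.39, Arhgap11a at 5.59 and Tmem63b at 8.13 in replicate 5. All are log2 signals.

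The short-term effect differed between the cell types for 19 genes, by an interaction term in the fit with one spread for both cell types. The differences, endothelial minus tumour, were 2.66 for Serpina3n, 2.16 for Rnf167, -3.04 for Kcnj2, -2.11 for Sez6l2, -2.01 for Galnt3, -1.93 for Igfbp3, -1.89 for Sema3c and -1.73 for Nes. List medians of that difference were -0.22 for hypoxia response, -0.15 for oxidative phosphorylation, -0.35 for the unfolded protein response, -0.55 for mitosis, -0.30 for p53 targets, -0.06 for tip cell genes, -0.28 for arterial markers and -1.01 for macrophage markers, each with adjusted p = 0.66 with an estimated correlation except oxidative phosphorylation at 0.73. For the long-term effect they were -0.83 for mitosis, -0.16 for endothelial junction genes, -0.66 for arterial markers, 0.40 for dissociation and immediate early genes and 0.16 for ribosomal proteins, with adjusted p between 0.28 and 0.67 with an estimated correlation. The effects of both treatment times differed in tumour cells for 243 genes, by the direct comparison of long-term with short-term cells.

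Of 13767 transcript clusters with no single gene name, used in no other comparison, 29 were called for short-term and 8 for long-term against untreated tumour cells, 1 for short-term against untreated and 1 for long-term against short-term endothelial cells, 10 and 3 for the differing short-term and long-term effects, and 562 for untreated endothelial against tumour cells.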

How the results depend on the processing

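The covariate fits and the removal of 3 macrophage-rich endothelial arrays were chosen after seeing the data, and the other alternatives before. Across alternatives other than leaving out an array, 133 counts stayed within 1.5 times their value and 44 moved, and 0 genes turned direction while called. Where no reason is given the cause was not tested.

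One fit over all 23 arrays, which shares one spread between cell types, gave 30, 9 and 96 genes for short-term, long-term and long-term against short-term tumour cells, 106, 34 and 262 for the same endothelial comparisons, and overlaps of 2 in tumour and 15 in endothelial cells. Array weights gave 67 and 10 genes for short-term and long-term tumour cells, 11 and 2 for the differing short-term and long-term effects, and 9 lists for the latter. Median centring gave 31 genes for long-term tumour cells and 3 lists for the differing short-term effect. A prior variance trend gave 2 genes for long-term endothelial cells. The isolation stress covariate gave 1 and 57 genes for short-term and long-term against short-term tumour cells, with 7 and 5 lists. For the 101 and 243 genes called without it, the median change went from 1.04 to 0.93 and from 0.84 to 0.80. All of them kept their sign (101 of 101 and 243 of 243), which is favoured for genes called in the same arrays. The macrophage covariate gave 10 lists for short-term and 12 for long-term against short-term endothelial cells. Long-term against short-term endothelial lists numbered 12 and 11 with filters at the 30th and 50th percentile and 10 after quantile normalization, and the differing short-term effect had 3 and 3 with these filters.

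With an estimated correlation camera passed 0 lists for short-term, 2 for long-term and 0 for long-term against short-term tumour cells, and 0, 0 and 0 for the endothelial comparisons. Fry passed 3, 2 and 0 in tumour cells and 0, 1 and 0 in endothelial cells. Both passed 0 and 0 for the differing short-term and long-term effects.

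Lists that turned direction in short-term tumour cells with the isolation stress covariate were mitosis (adjusted p = 0.000716), DNA replication (0.483), epithelial genes (0.937) and epithelial tumour cell markers (0.973). With the macrophage covariate macrophage markers did so in short-term (0.842) and long-term against short-term endothelial cells (0.44), where the covariate is the mean of the same genes. Over 24 alternatives each, these adjusted p ran from 1.37e-15 to 0.576, 7.25e-05 to 0.576, 0.000363 to 0.937, 0.000973 to 0.973, 5.6e-10 to 0.842 and 1.82e-08 to 0.44, in the order named.

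Deviations of arrays from their group means correlated weakly between replicates that share a number. Across treatments 10 pairs of tumour cell arrays correlated at -0.102 to 0.082 and 9 endothelial pairs at -0.149 to 0.112. Across cell types 11 pairs correlated at -0.11 to 0.064. Pairs with different numbers were not set beside them, so shared animals or pools are not excluded. The number as a block gave 85, 2 and 276 genes in tumour cells and 0, 0 and 0 in endothelial cells.

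Leaving out 1 array gave 23 to 105, 5 to 30 and 95 to 307 genes in the tumour cell comparisons, 0 to 2, 0 to 1 and 0 to 5 in the endothelial ones, 1 to 138 and 0 to 5 for the differing short-term and long-term effects and 2692 to 4138 between untreated cell types. Lists ran from 11 to 16, 9 to 10 and 12 to 15, from 4 to 9, 8 to 22 and 15 to 21, and from 3 to 11 and 4 to 12. The long-term endothelial lists numbered 22 and 8 without untreated replicates 1 and 2. How far signals lay above array background was not tested.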

Other observations

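The lists described here were picked from the fixed lists after the results were seen. Under long-term treatment endothelial cells had list shifts beyond glycolysis and hypoxia, with 0 genes called by limma over all genes and 833 at an unadjusted p under 0.05. Endothelial activation and adhesion genes had a median of 0.58, 11 of 14 positive and 1 passing adjusted over the list alone, with adjusted p = 0.12 with an estimated correlation. Lactate and monocarboxylate transport genes had a median of 0.35, 9 of 11 positive, and TCA cycle genes 0.30, 18 of 21 positive, with adjusted p = 0.14 and 0.16 with an estimated correlation. Type I interferon genes had a median of -0.21, with 6 of 28 positive and adjusted p = 0.20 with an estimated correlation. Of the 56 splits of these arrays, 2, 4, 6 and 4 gave as small a p in either direction for these lists, in the order named.

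In short-term tumour cells collagen and matrix genes had a median of 0.18, with 2 of 23 rising over all genes, 4 passing adjusted over the list alone and adjusted p = 0.32 with an estimated correlation. P53 targets had a median of 0.24, with 0 of 18 called by limma, 3 passing adjusted over the list alone and adjusted p = 0.44 with an estimated correlation. In long-term tumour cells mitosis genes had a median of 0.34, with 30 of 31 positive, 0 called by limma, 0 adjusted over the list alone and adjusted p = 0.65 with an estimated correlation. As small a p in either direction came from 4 and 1 of 35 splits for the matrix genes and p53 targets, and from 19 of 56 for mitosis.

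The macrophage marker mean was 7.36 in untreated endothelial replicate 1 against 5.33 and 5.52 in the other untreated arrays, and 7.32 and 6.52 in long-term replicates 3 and 4. Krt19, at 9.56 in long-term endothelial replicate 4, had group means of 3.67, 3.81 and 3.62 in untreated, short-term and long-term tumour cells. The source of this signal was not tested. Among genes outside the naming rule, chosen after their values were seen, Snora73a (3.54), Snora73b (3.25) and Snora52 (3.07) had higher short-term effects in endothelial than in tumour cells.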
